A study of Homo sapiens with 6 samples.

How the data were processed

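The series holds RNA-seq of 6 libraries of 1 human cell line in 2 groups, control siRNA (3 libraries) and IGF2BP3 siRNA (3 libraries), grouped by the transfection given in the labels. Per the submitters' processing notes, the tools were TopHat2 (2.0.11), TopHat and HTSeq, and the build was hg19, also called GRCh37. The notes give no order of steps, and the annotation release, the strand setting and the treatment of multi-mapped reads are not given in the sources used here. The deposited values are whole-number read counts per gene, not normalized by the authors, in 1 file per library. Each file lists 60483 versioned Ensembl gene IDs, with no row for unassigned reads, and library sizes are sums over all rows. The ID versions belong to annotations of a later build than the one in the notes, 61.45% being identical in GENCODE 29, and for this reason no coordinates are given. Gene symbols were taken by ID without the version from a gene name reference, and from GENCODE 29 where that gave none. In all, 56753 rows received a symbol. All 37 mitochondrial gene rows were at 0 in every library.

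Before averaging, replicates were compared by a chi-square of their counts over genes. It came to between 9.49 and 96.0 per degree of freedom in the 6 pairs within groups, so no pair agreed within sampling noise and each library counted as 1 replicate. Total counts lay between 17127806 and 18495521.

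The main test was edgeR (4.0.16) in R (4.3.3), with TMM normalization, filterByExpr at its defaults (minimum count 10, minimum total count 15), glmQLFit at the defaults of that version, and glmQLFTest for IGF2BP3 siRNA against control siRNA, with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A change of at least 2-fold meant an absolute log2 change of at least 1. Standard errors of log2 changes were derived from the quasi-likelihood F statistic. CPM values are TMM-normalized unless stated otherwise. Gene lists were tested with camera in limma (3.58.1) on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 31 of 32 lists that had at least 3 tested genes. An estimated correlation and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, were the alternatives. The lists, the named genes and the tests were fixed before the data were examined, except 2 liver lists and those alternatives named as chosen later. Named genes were IGF2BP1 to IGF2BP3, the 8 largest changes in each direction among called protein-coding genes with a mean CPM of at least 5 and no overlap between groups, the 3 called members with the smallest p of each list past the threshold, and the 1 such member of each other list. Some genes, 1 gene list and the tests that need them are not reported here. Exons of 8 of the 56 named genes overlap those of another tested gene. None of them shares 20% or more of its exon bases with a gene of at least 0.2 of its CPM. Library measures were compared with exact two-sided permutation tests in Python (3.11.15) with scipy (1.17.1).

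Fixed before the data were examined were DESeq2 (1.42.0), limma-voom, other scaling factors (RLE, upper quartile, library size alone), no filter or a CPM of at least 1 in 3 libraries, the replicate number as a block, and leaving out each library. Chosen after the data were seen were edgeR with bias-adjusted deviances, limma-voom with sample quality weights and an offset that removes each library's lowess trend (span 0.3) with transcript length, alone, with the block and without knockdown replicate 1. The scripts were tested on simulated counts for this comparison over 15157 genes, 200 of them changed. With the spread of all 6 libraries, edgeR recovered 43% of 100 genes changed 2-fold and 88% of 100 changed 4-fold with 12 false calls, and camera recovered its shifted list with 0 false lists. With the spread without knockdown replicate 1 it recovered 82% and 95%, with 8 false calls. A length trend with no changed gene was also simulated, at 0.3 log2 units less per doubling of length in all 3 knockdown libraries. There the uncorrected fit made 115 false calls at the first spread and 2939 at the second, and the length offset 0 and 1.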

Results

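RNA-seq read counts per gene were available for 6 libraries from a human cell line named PC3 in the labels, which also describe it as a lung cancer line. PC-3 is otherwise known as a prostate carcinoma line. Cells at passages 16 to 19 were transfected with a control siRNA (3 libraries) or with an siRNA against IGF2BP3 (3 libraries, called knockdown here). IGF2BP3 is an RNA-binding protein of the insulin-like growth factor 2 mRNA-binding family, known from fetal tissue and many tumors. The comparison addresses which transcripts change after the siRNA against IGF2BP3. The labels name no second siRNA against this gene and no re-expression of it. Other effects of the siRNA therefore cannot be told apart from those of IGF2BP3 depletion. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Total counts were 17749439, 18260310 and 18495521 in control replicates 1 to 3 and 17134865, 17127806 and 17882111 in knockdown replicates 1 to 3. The totals did not separate the groups (exact two-sided permutation p = 0.2; 3 against 3 cannot go below 0.1). The knockdown libraries held more genes with at least 1 count, 25658 ± 1305 against 24227 ± 104 (SD, n = 3 each, exact permutation p = 0.1). Their 10 most abundant genes took 5.33% ± 0.917 of the counts against 6.50% ± 0.296 in the controls (SD, n = 3 each, exact permutation p = 0.1).

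IGF2BP3 itself (ENSG00000136231.12) was 4.57-fold lower after its siRNA. Its level was 123, 134 and 114 CPM (normalized counts relative to library size) in control replicates 1 to 3 and 19.3, 38.9 and 22.9 CPM in knockdown replicates 1 to 3. In log2 units the change was -2.19 ± 0.26 (SE), with an adjusted p of 0.0216 (edgeR quasi-likelihood test, Benjamini-Hochberg), and all 3 knockdown libraries lay below all 3 controls. The related IGF2BP1 stood at 268 ± 38.3 CPM against 412 ± 27.3 in the controls (SD, n = 3 each), a log2 difference of -0.62 ± 0.15 that did not pass the threshold (edgeR adjusted p = 0.0556). IGF2BP2 did not pass it either, at -0.25 ± 0.15 (edgeR adjusted p = 0.331). Without knockdown replicate 1 both passed, IGF2BP1 at -0.54 (edgeR adjusted p = 0.00598) and IGF2BP2 at -0.40 (edgeR adjusted p = 0.00948). With the trend with transcript length also removed, only IGF2BP3 and 1 of these 2 genes were called lower. Leaving out control replicate 1, control replicate 2 or knockdown replicate 3 ended the IGF2BP3 call (edgeR adjusted p = 0.150, 0.134 and 0.0733), while its log2 change stayed between -2.55 and -2.00 in the 6 fits without 1 library. The exons of IGF2BP3 share 17.9% of their bases with MALSU1 on the opposite strand, and the strand setting of the counting is not given in the sources used here, so part of the remaining counts cannot be assigned to either gene.

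**Figure D1:**
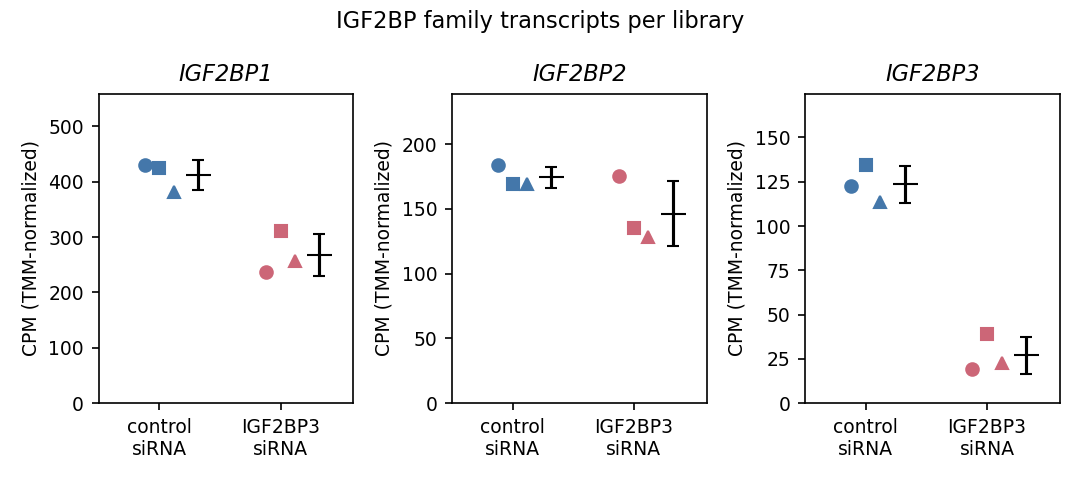
TMM-normalized CPM of IGF2BP1, IGF2BP2 and IGF2BP3 in each library (vertical axes, starting at 0). Circles, squares and triangles are replicates 1, 2 and 3, and the black marks are the group mean ± SD (n = 3). The 3 knockdown libraries lie at 19.3 to 38.9 CPM for IGF2BP3, all below the controls at 114 to 134.

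Across the transcriptome, 348 genes rose and 277 fell after the knockdown among 15157 tested (625 genes, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Large changes were mostly increases, since 249 of the genes that rose but 84 of those that fell changed at least 2-fold; without knockdown replicate 1 these counts were 575 and 396. Protein-coding genes made up 585 of the 625. In 33.7% of the tested genes the 3 libraries of one group all lay above the 3 of the other, where chance gives 10%. Library size alone as the scaling gave 302 genes higher and 104 lower, and upper-quartile scaling gave 441 and 202. Knockdown replicate 1 stood apart from the other knockdown libraries: on the plot of principal components it lay at 61.0 on the first (48.2% of variance), against 14.9 and 22.1 for knockdown replicates 2 and 3. The count of changed genes depended on single libraries. Without knockdown replicate 1, 4610 genes were called (2235 higher, 2375 lower), which included all 625 in the same direction. Knockdown replicates 2 and 3 had a trend with transcript length. Its slopes were -0.061 and -0.119 per doubling, against 0.030 to 0.050 in the controls. A steeper trend, simulated in all 3 knockdown libraries, gave 2939 false calls at the spread without replicate 1. How many calls the observed trend would give was not simulated. With the trend of each library also removed, a fit chosen after the data were seen, edgeR called 3543 genes (1880 higher, 1663 lower), 2930 of them among the 4610. Without control replicate 3, 43 were called, and without knockdown replicate 2 only 1. Without control replicate 1, control replicate 2 or knockdown replicate 3, edgeR called 0 genes, while 2479, 2600 and 3343 had an unadjusted p under 0.05.

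**Figure D2:**
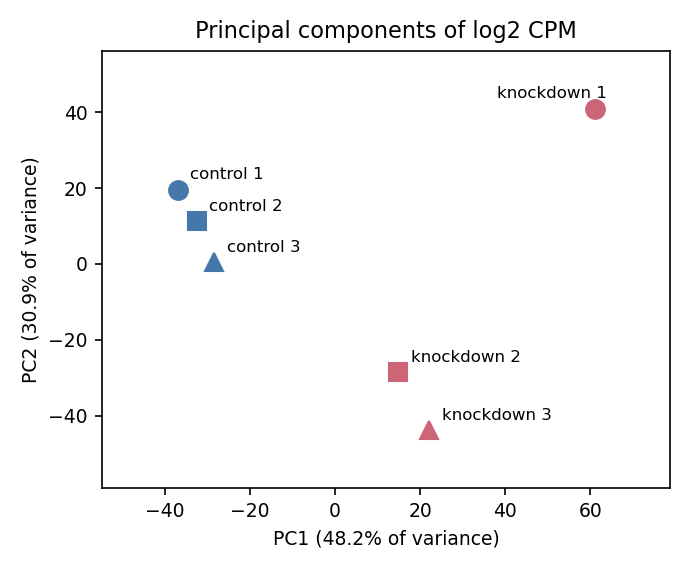
First and second principal components of log2 CPM in the 6 libraries (axis values are component scores). Blue marks are control and red marks knockdown libraries. The controls lie between -37.1 and -28.4 on the first component, and knockdown replicate 1 lies farthest from them, at 61.0.

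The largest increases were taken among called genes with a mean CPM of at least 5, some of them low in the controls. They were in CRABP2, a retinoic acid carrier, at 4.57 ± 0.79 on the log2 scale, and IL11, a cytokine of the interleukin-6 family, at 3.99 ± 0.68. MAPK8IP2, a scaffold of the JNK pathway, followed at 3.36 ± 0.74, the smooth muscle protein gene CNN1 at 3.11 ± 0.43 and the transcriptional repressor ZEB2 at 3.08 ± 0.55. ACHE, which encodes acetylcholinesterase, rose by 3.01 ± 0.67, the TNF receptor family gene TNFRSF9 by 3.00 ± 0.59 and the methyltransferase gene NNMT by 2.98 ± 0.27. Several of these were highest in knockdown replicate 1. CRABP2, for example, was at 28.6, 5.77 and 4.94 CPM in knockdown replicates 1 to 3 and at 0.505 to 0.615 CPM in the controls. CRABP2 had 9 to 11 counts per control library and MAPK8IP2 had 10 to 23. Without knockdown replicate 1 the change was 3.37 for CNN1, 3.28 for CRABP2, 3.02 for NNMT and 2.99 for IL11. It was 2.39 for ZEB2, 2.26 for TNFRSF9, 2.11 for MAPK8IP2 and 1.83 for ACHE. The largest decrease was in ATP2B2, a plasma membrane calcium pump, at -2.65 ± 0.35, from 108 ± 46.0 to 17.2 ± 4.90 CPM (SD, n = 3 each). After IGF2BP3 itself, genes of secreted liver proteins followed, with APOB (apolipoprotein B) at -1.96 ± 0.26, AHSG (fetuin-A) at -1.95 ± 0.35 and ITIH2 (an inter-alpha-trypsin inhibitor chain) at -1.94 ± 0.21. APOB went from 6650 ± 1564 to 1711 ± 403 CPM (SD, n = 3 each). ADH6, an alcohol dehydrogenase gene, fell by 1.77 ± 0.37, PRLR, the prolactin receptor gene, by 1.75 ± 0.36, and SCD, the stearoyl-CoA desaturase gene, by 1.68 ± 0.26. The edgeR adjusted p of these 15 genes lay between 0.0200 and 0.0490. With limma-voom, CRABP2, IL11, MAPK8IP2, ZEB2, ACHE, TNFRSF9, ADH6 and PRLR no longer passed, at adjusted p between 0.0501 and 0.0925. With library size alone AHSG, MAPK8IP2, ACHE, TNFRSF9, ADH6 and PRLR no longer passed (edgeR adjusted p between 0.0501 and 0.0590), and with a correction for transcript length chosen after the data were seen ACHE (2.98 ± 0.68, 0.0550) and PRLR (-1.46 ± 0.32, 0.0508). MAPK8IP2 and ACHE were also lost with bias-adjusted deviances (0.0555 and 0.0536).

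Of 25 tested NF-kB response and cytokine genes, 13 rose over all genes tested and 17 adjusted over the list alone, and none fell (median log2 change 0.84, camera adjusted p = 4.72e-10, adjusted p = 0.258 with an estimated correlation). TNF went from 1.48 ± 0.269 to 9.55 ± 1.34 CPM (log2 change 2.68 ± 0.24), IL6 from 0.356 ± 0.0830 to 2.86 ± 0.963 CPM (2.98 ± 0.40), and LIF from 2.79 ± 1.27 to 13.3 ± 3.28 CPM (2.25 ± 0.35; SD of CPM and SE of the log2 change, n = 3 each). IL6 had 5 to 8 counts per control library. Of 15 antigen presentation and checkpoint ligand genes, 4 rose (9 adjusted over the list alone) and all 15 had a positive change (median 0.80, camera adjusted p = 1.43e-05, adjusted p = 0.258 with an estimated correlation). Among them were the class I molecules HLA-E (1.57 ± 0.26) and HLA-C (1.08 ± 0.21) and the peptide transporter subunit TAP1 (2.12 ± 0.33), with HLA-C chosen after its values were seen. The class I gene HLA-B, also chosen after its values were seen, was not called (0.21 ± 0.21, edgeR adjusted p = 0.573). HLA class I genes are near-identical in places, and how reads shared among them were counted is not given in the sources used here. Of 22 immediate early genes, 4 rose (8 adjusted over the list alone): FOSB (2.02 ± 0.31), JUNB (1.70 ± 0.26), the ERK phosphatase gene DUSP5 (0.90 ± 0.14) and KLF4 (2.17 ± 0.42, chosen after its values were seen). Their median change was 0.59 (camera adjusted p = 2.01e-05, adjusted p = 0.258 with an estimated correlation). Of 26 interferon-stimulated genes, 2 rose (6 adjusted over the list alone), ISG15 by 1.38 ± 0.15 and IFI6 by 2.44 ± 0.40 (list median 0.62, camera adjusted p = 2.75e-04, adjusted p = 0.258 with an estimated correlation). The interferon list stood at 1.26 above the control mean in knockdown replicate 1 and at 0.52 and 0.41 in knockdown replicates 2 and 3, and the immediate early list at 0.86 against 0.56 and 0.46.

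Of 24 cholesterol synthesis genes, 3 fell (10 adjusted over the list alone) and 1 had a positive change (median -0.70, camera adjusted p = 6.66e-06, adjusted p = 0.413 with an estimated correlation). Among them, the sterol transport gene STARD4 fell by 0.65 ± 0.13 and SREBF2, the master regulator of the pathway, by 0.59 ± 0.13. The median of this list lay at -1.60 in knockdown replicate 1 and at -0.40 and -0.46 in knockdown replicates 2 and 3, relative to the control mean. With the replicate block STARD4 and SREBF2 no longer passed (edgeR adjusted p = 0.0619 and 0.0716), though their log2 changes stayed at -0.65 ± 0.16 and -0.60 ± 0.15, with a wider spread. STARD4 was also lost with library size alone (-0.58 ± 0.13, 0.0564), and SREBF2 with library size alone (-0.53 ± 0.14, 0.0783), upper-quartile factors (-0.54 ± 0.13, 0.0544) and the length correction (-0.49 ± 0.11, 0.0549). Of 15 fatty acid synthesis genes, 4 fell (9 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 6.43e-05, adjusted p = 0.258 with an estimated correlation). FASN, the fatty acid synthase gene, went from 1069 ± 133 to 396 ± 97.0 CPM and SCD from 1662 ± 315 to 518 ± 156 CPM (SD, n = 3 each). ACACA, an acetyl-CoA carboxylase gene, fell by 0.97 ± 0.16, and SREBF1, chosen after its values were seen, by 0.86 ± 0.15. Unlike the cholesterol list, this list had similar medians in the 3 knockdown libraries (-0.52, -0.56 and -0.76); the difference between the lists was not tested.

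Of 38 G2 and mitosis genes, 5 fell (9 adjusted over the list alone): ASPM (-1.14 ± 0.14), the proliferation marker MKI67 (-1.57 ± 0.25), CENPE (-0.94 ± 0.18) and, chosen after their values were seen, TOP2A (-0.68 ± 0.13) and CENPF (-0.74 ± 0.15). The median was -0.35 (camera adjusted p = 1.31e-05, adjusted p = 0.413 with an estimated correlation), and without knockdown replicate 1 it was -0.18, with 1 gene called higher and 14 lower. MKI67 went from 876 ± 78.7 to 295 ± 104 CPM (SD, n = 3 each). Of 41 DNA replication and S phase genes, 2 fell (3 adjusted over the list alone), among them the DNA polymerase gene POLA1 by 0.80 ± 0.17, with a median of -0.32 (camera adjusted p = 2.01e-05, adjusted p = 0.413 with an estimated correlation). Both lists were lowest in knockdown replicate 1, at -0.76 and -0.56, against -0.15 to -0.28 in knockdown replicates 2 and 3. Without replicate 1 the S phase median was -0.26, with 1 gene called higher and 20 lower. With the length correction MKI67, CENPE and POLA1 no longer passed (edgeR adjusted p = 0.0702, 0.0699 and 0.0807), with log2 changes of -1.21 ± 0.31, -0.71 ± 0.18 and -0.68 ± 0.19. CENPE was also lost with library size alone (-0.88 ± 0.19, 0.0552). The cyclin-dependent kinase inhibitor gene CDKN1A rose by 1.80 ± 0.28. Of 21 apoptosis regulators, BIK, a pro-apoptotic BCL2-family gene, rose by 3.50 ± 0.47 from 3 to 8 counts per control library, and BIRC3, an inhibitor of apoptosis, by 1.20 ± 0.26. In the apoptosis list 6 genes were higher adjusted over the list alone (median 0.25, camera adjusted p = 0.00715, adjusted p = 0.264 with an estimated correlation). Its median was 0.12 in knockdown replicate 1 and 0.35 and 0.47 in replicates 2 and 3, and without replicate 1 the median change was 0.42, with 11 genes called higher.

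Of 21 mesenchymal and matrix genes, 5 rose (6 adjusted over the list alone), among them ZEB2, the membrane protease gene MMP14 (0.96 ± 0.20), the transcription factor gene SNAI1 (0.87 ± 0.18) and the collagen gene COL1A2 (1.38 ± 0.29). COL1A2 no longer passed with limma-voom (1.31 ± 0.29, adjusted p = 0.0536) or library size alone (1.47 ± 0.33, edgeR adjusted p = 0.0582). The median was 0.42 (camera adjusted p = 0.00212, adjusted p = 0.273 with an estimated correlation). SNAI1 no longer passed with the length correction (0.73 ± 0.19, edgeR adjusted p = 0.0756) or library size alone (0.95 ± 0.20, 0.0539). Epithelial junction and keratin genes did not pass as a list (median 0.36, camera adjusted p = 0.213): of 16 tested, SPINT1, a protease inhibitor gene, rose by 1.10 ± 0.18 and CLDN4, chosen after its values were seen, by 1.65 ± 0.36, with 5 higher and 1 lower adjusted over the list alone. TGF-beta response genes did not pass with all 6 libraries (median 0.18, camera adjusted p = 0.0877) and passed without knockdown replicate 1 (median 0.35, camera adjusted p = 0.0184, adjusted p = 0.337 with an estimated correlation). Of the 18 tested 3 rose, among them INHBA, an activin subunit gene, by 3.31 ± 0.48, and JUNB. INHBA had 4 to 10 counts per control library. SKI, a repressor of the pathway chosen after its values were seen, fell by 0.83 ± 0.14. Adjusted over the list alone, 6 were higher and 2 lower. None of 18 Notch pathway genes was called, also when adjusted over the list alone (median 0.23, camera adjusted p = 0.321). The Notch median was 0.64 in knockdown replicate 1 and 0.08 and -0.07 in replicates 2 and 3, and without replicate 1 it turned to -0.04, with 2 genes called higher and 6 lower (camera direction down, adjusted p = 0.710). With the length trend also removed it was 0.10, with 1 gene called higher and 2 lower (camera direction up, adjusted p = 0.644).

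The ATF4 and amino acid response list differed between the knockdown libraries. Its median lay at 1.10 above the control mean in knockdown replicate 1 and at 0.05 and 0.10 in knockdown replicates 2 and 3. Over all libraries the median change was 0.54 (camera adjusted p = 0.00715, adjusted p = 0.582 with an estimated correlation), and without knockdown replicate 1 it was 0.10 (camera adjusted p = 0.592). Of 32 tested genes, 2 rose (5 higher and 1 lower adjusted over the list alone): CEBPB, a transcription factor gene, by 1.08 ± 0.13, with 70.0, 68.5 and 80.4 CPM in knockdown replicates 1 to 3 against 32.5 to 37.7 in the controls, and VLDLR, a lipoprotein receptor gene, by 1.97 ± 0.42, from 5.80 ± 1.28 to 22.8 ± 14.3 CPM (SD, n = 3 each), with 39.2 CPM in knockdown replicate 1. VLDLR no longer passed with limma-voom (1.83 ± 0.45, adjusted p = 0.0630) or library size alone (2.08 ± 0.46, edgeR adjusted p = 0.0564). Its change without knockdown replicate 1 was 1.32 (edgeR adjusted p = 0.00148). None of the 56 cytosolic ribosomal protein genes was called, also when adjusted over the list alone, and all 56 had a positive change (median 0.30, camera adjusted p = 2.01e-05, adjusted p = 0.582 with an estimated correlation). Their median was -0.11 in knockdown replicate 1 and 0.32 and 0.52 in knockdown replicates 2 and 3, and without replicate 1 edgeR called 53 of them higher, or 31 with the length trend also removed (median 0.43 and 0.29). In that uncorrected fit the shortest 20% of all genes had a median of 0.25. The hypoxia and glycolysis list passed with 1 of 31 genes called, also adjusted over the list alone, the enolase gene ENO2 (2.34 ± 0.34; list median 0.25, camera adjusted p = 0.0288, adjusted p = 0.258 with an estimated correlation). NRF2 and ferroptosis genes did not pass with all libraries (28 tested, median 0.14, camera adjusted p = 0.321) and passed without knockdown replicate 1 (median 0.24, camera adjusted p = 0.0184, adjusted p = 0.337 with an estimated correlation). In that fit 10 were called higher and 3 lower. The list median was -0.13 in knockdown replicate 1 and 0.17 and 0.21 in replicates 2 and 3. With all libraries the heme oxygenase gene HMOX1 was the 1 member called, also adjusted over the list alone, at 1.02 ± 0.12. Among 14 heat shock genes the small heat shock protein gene HSPB1 rose by 0.98 ± 0.16, the 1 call also when adjusted over the list alone, while the list median was -0.40 (camera adjusted p = 0.203) and lay at -0.87 in knockdown replicate 1. No gene was called, over all genes or adjusted over the list alone, among 23 ER chaperone genes (median 0.05, mean -0.04, camera direction down, adjusted p = 0.478), 37 nuclear-encoded respiratory chain genes (median 0.10, camera adjusted p = 0.118) or 11 replication-dependent histone genes (median -0.47, camera adjusted p = 0.0877). Without knockdown replicate 1 the respiratory chain list passed (median 0.30, camera adjusted p = 1.10e-04, adjusted p = 0.464 with an estimated correlation), with 18 genes called higher and 1 lower. With the length trend also removed its median was 0.19, with 11 higher (camera adjusted p = 0.00293, adjusted p = 0.525 with an estimated correlation). With all 6 libraries it passed with library size alone (camera adjusted p = 0.0454). The histone list, whose median was -1.25 in knockdown replicate 1, passed without control replicate 3, knockdown replicate 2 or knockdown replicate 3 (camera adjusted p = 0.0226, 0.0139 and 0.0151), and with library size alone (0.0437) or the length correction (0.0137). Over all 6 libraries it had an adjusted p = 0.664 with an estimated correlation. Without knockdown replicate 1 its median was -0.15, with 3 genes called lower (camera adjusted p = 0.398). With the length trend also removed the histone list passed at a median of -0.38, with 4 lower (camera adjusted p = 0.0280, adjusted p = 0.351 with an estimated correlation). The mitochondrially encoded genes, meant as a sign of RNA quality, were listed at 0 counts in all 6 libraries, while pseudogenes of mitochondrial origin took 0.215% to 0.475% of the counts. Whether mitochondrial reads were removed, or not counted under the annotation used, is not given in the sources used here, so the zeros say nothing of RNA quality and that list was not tested.

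Of 26 microRNA machinery and RNA decay genes, TNRC6A, a partner of Argonaute proteins, fell by 0.79 ± 0.13 and DICER1 by 0.92 ± 0.20; 1 was higher and 4 lower adjusted over the list alone (median -0.21, camera adjusted p = 0.00177, adjusted p = 0.413 with an estimated correlation). The median of this list was -0.06 in knockdown replicate 1 and -0.32 and -0.43 in replicates 2 and 3, and without replicate 1 it was -0.37, with 15 genes called lower, or 10 with the length trend also removed. TNRC6A no longer passed with the length correction (-0.55 ± 0.15, edgeR adjusted p = 0.0817), and DICER1 with library size alone (-0.84 ± 0.24, 0.0874) or upper-quartile factors (-0.86 ± 0.21, 0.0580). Of 20 m6A writers, erasers and readers none was called, also when adjusted over the list alone (median -0.27, camera adjusted p = 0.0139, adjusted p = 0.258 with an estimated correlation, 0.0957 with the length correction). The m6A median was -0.28 in knockdown replicate 1 and -0.09 and -0.14 in replicates 2 and 3, and without replicate 1 it was -0.09, with 8 genes called lower, or 2 with the length trend also removed (camera adjusted p = 0.0294 and 0.383, the former lost at adjusted p = 0.337 with an estimated correlation). The IGF2BP family list of 3 contains the siRNA target, which fixed its outcome, and it passed with IGF2BP3 alone called (2 lower adjusted over the list alone, median -0.62, camera adjusted p = 0.00715, adjusted p = 0.258 with an estimated correlation). Transcripts reported elsewhere as bound by IGF2BP3 or dependent on it did not shift as a list (17 tested, median 0.02, mean 0.18, camera direction down, adjusted p = 0.932). CD44, a hyaluronan receptor gene, rose by 1.75 ± 0.26, from 48.9 ± 16.9 to 164 ± 19.9 CPM (SD, n = 3 each). Chosen after their values were seen, LAMB3 rose by 2.84 ± 0.50 and the chromatin protein gene HMGA2 fell by 1.21 ± 0.20; 4 were higher and 3 lower adjusted over the list alone. With the preset correlation of camera, 17 of the 31 testable lists passed, while the other ways of dividing the 6 libraries into 3 and 3 put 7 to 14 lists past the threshold. With fry, the lists of G2 and mitosis (adjusted p = 0.0806), S phase (0.0845), microRNA machinery (0.115), cholesterol synthesis (0.118), ATF4 response (0.299) and ribosomal proteins (0.299) no longer passed, while TGF-beta response and fibroblast markers did (0.0463 each).

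**Figure D3:**
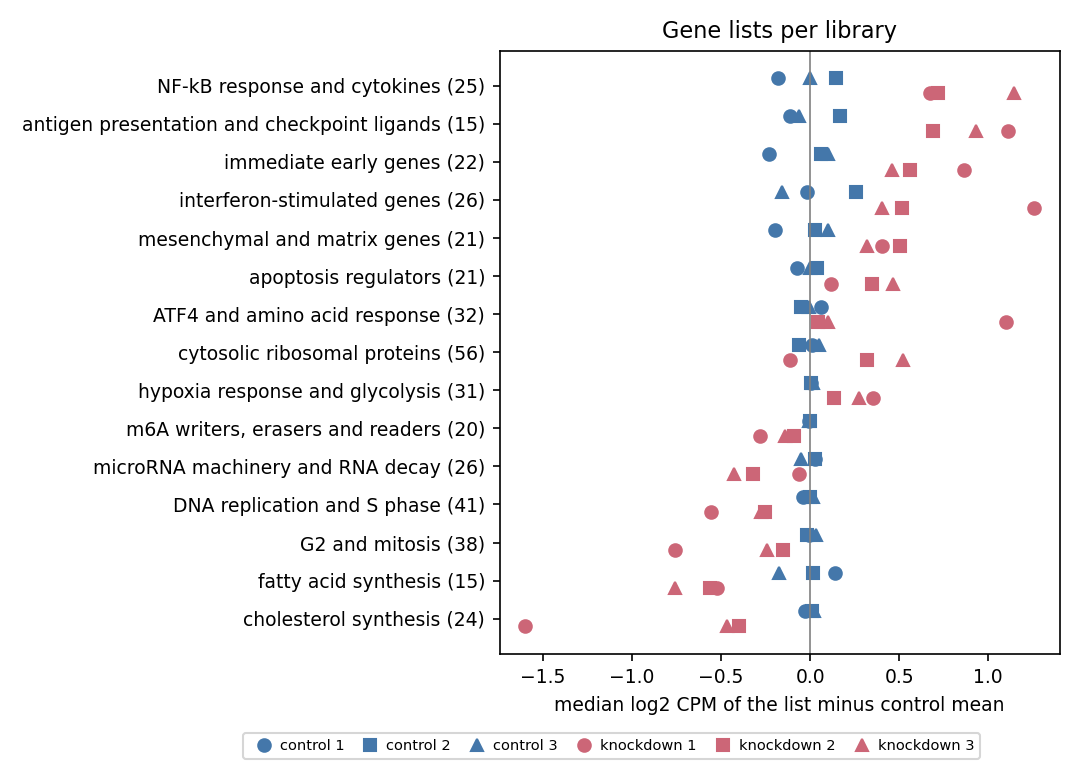
Median over the genes of each list of log2 CPM minus the control mean (horizontal axis), per library, with the number of tested genes in brackets. Blue marks are control and red marks knockdown libraries, and circles, squares and triangles are replicates 1, 2 and 3. Knockdown replicate 1 lies at 1.10 for the ATF4 list and at -1.60 for cholesterol synthesis, where replicates 2 and 3 lie at 0.05 and 0.10 and at -0.40 and -0.46.

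Lineage markers were read as levels in all 6 libraries. The most abundant gene was AFP, alpha-fetoprotein, at a mean of 9020 CPM (without TMM scaling, as are the levels that follow), with APOB at 4133, albumin (ALB) at 3735 and SERPINA1, alpha-1-antitrypsin, at 2180 CPM. Of 40 liver-secreted and hepatocyte genes, a list chosen after the data were seen, 36 had at least 1 CPM, and together they took 3.45% ± 0.659 of the counts in the controls and 2.08% ± 0.117 in the knockdown libraries (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Among 18 prostate lineage genes 8 reached 1 CPM, and KLK3, prostate-specific antigen, was at 0.365 CPM. Among 20 lung epithelial genes 7 reached 1 CPM, led by FOXA2 at 78.8 and FOXA1 at 77.6 CPM, which liver cells also express, whereas the lung regulator NKX2-1 had 1 read in the 6 libraries. Tested as lists, prostate (8 tested, median -0.02, mean 0.09, camera direction down, adjusted p = 0.942) and lung markers (7 tested, median -0.22, mean 0.21, camera direction down, adjusted p = 0.411) did not pass, with 0 genes called. Adjusted over the list alone, 1 prostate gene was higher and 1 lower, and 0 lung genes were called. Blood and endothelial markers had 0 called genes (9 tested, median -0.18, camera adjusted p = 0.411), also when adjusted over the list alone. Fibroblast and smooth muscle markers had COL1A2 called higher (8 tested, 2 adjusted over the list alone, median 0.33, camera adjusted p = 0.203, or 0.0280 without knockdown replicate 1 and with the length trend removed, where the adjusted p = 0.343 with an estimated correlation). The neuroendocrine list passed (median 0.43, camera adjusted p = 0.0377, adjusted p = 0.264 with an estimated correlation), with ENO2 and CHGB called of 5 tested, also adjusted over the list alone, where CHGB had 2 to 3 counts per control library and 10 to 13 per knockdown library. CHGB no longer passed with the replicate block (edgeR adjusted p = 0.0700) or with no filter on low counts (0.0510). That list no longer passed without control replicate 3, knockdown replicate 1 or knockdown replicate 3 (camera adjusted p = 0.0534, 0.123 and 0.0569), nor with library size alone (0.0584), the replicate block (0.0576) or a minimum of 1 CPM in 3 libraries (0.223).

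**Figure D4:**
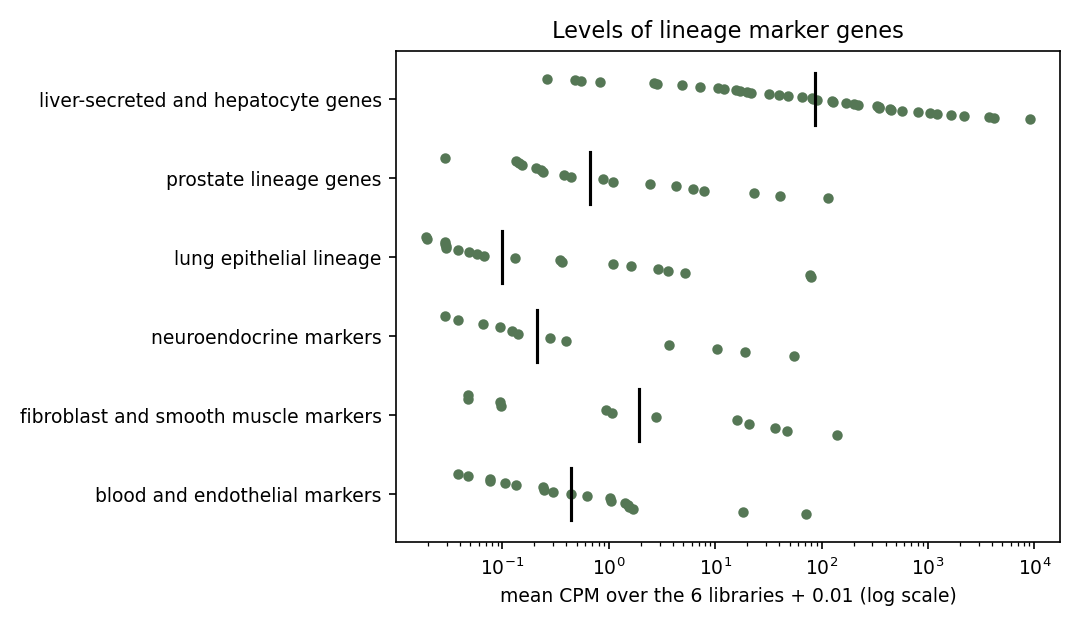
Mean CPM over the 6 libraries plus 0.01 (horizontal axis, log scale) of each gene of 6 lineage lists, 1 point per gene; black lines are list medians. The liver list has a median of 86.4 CPM, and the other lists have medians between 0.0896 and 1.92 CPM.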

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

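Tests with bias-adjusted deviances, quality weights and the length correction, also without knockdown replicate 1, were chosen after the results were seen. The 625 changed genes became 1792 with DESeq2, 406 with library size alone, 2332 with no filter on low counts, 4714 with limma-voom with sample quality weights, 3543 with the length correction and without knockdown replicate 1, and 0 to 4610 without 1 library. The 333 genes changed at least 2-fold became 724 with DESeq2, 1093 with no filter, 1036 with quality weights, 819 with the length correction and without knockdown replicate 1, and 0 to 971 without 1 library. Leaving out a library lowers the number of samples, and only the removal of knockdown replicate 1, the library farthest from its group (quality weight 0.134), raised the counts. The cause of the other shifts was not tested. The log2 change of IGF2BP3 stayed between -2.55 and -1.93 in all alternatives (-2.55 to -2.00 without 1 library, the latter without knockdown replicate 1) and lost its call without control replicate 1 (-2.21), control replicate 2 (-2.13) or knockdown replicate 3 (-2.09). The count of 17 lists fell to 0 with an estimated correlation (5 at an unadjusted p under 0.05, 14 lists with fry, 6 of the 17 being lost) and was 16 to 19 in the other alternatives. With an estimated correlation 0 lists also passed in every other split of the 6 libraries. Lists with an estimate below the preset 0.01 lost their calls too: the IGF2BP family (-0.012), m6A (7.1e-04), hypoxia (-0.023) and neuroendocrine lists (-0.18). For these lists the loss does not show that correlation between genes produced the calls. Estimates were far above the preset for ribosomal proteins (0.848), cholesterol synthesis (0.644), ATF4 response (0.436), S phase (0.363), mitosis (0.345) and microRNA machinery (0.269). Their camera p-values at the preset may therefore be too small, and these are the 6 lists lost with fry. Of the genes reported here, none called in either fit changed direction in any alternative. Of the 53 calls among the other named genes, 53 were lost without control replicate 1, control replicate 2, knockdown replicate 2 or knockdown replicate 3, 44 without control replicate 3, 13 with library size alone, 10 with limma-voom, 8 with the length correction and 3 with the replicate block.

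Whether replicate numbers pair the libraries is not given in the labels and stays open. Deviations of same-numbered libraries correlated at 0.157, -0.081 and 0.073, within the range of differently numbered ones (-0.163 to 0.191). With the replicate block 621 genes were called (453 of them shared with the 625), 397 at 2-fold or more, 16 lists passed, and IGF2BP3 was at -2.25. With the spread of all 6 libraries, 43% of simulated 2-fold changes were recovered, so genes not called may still have changed.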

Other observations

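Tests on the knockdown level and the share of calls kept after the length correction were chosen after those results were seen, as were the liver lists.

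The liver genes had lower list medians in knockdown replicates 1 to 3 (-0.68, -0.67 and -0.55 relative to the control mean) than in any control. Of 38 tested, 9 fell (16 lower and 1 higher adjusted over the list alone), with a median log2 change of -0.66 (camera adjusted p = 1.62e-07, adjusted p = 0.321 with an estimated correlation). Besides APOB, AHSG and ITIH2 these included ASGR1 (-1.51 ± 0.26), CPB2 (-1.44 ± 0.30), SERPINA1 (-0.99 ± 0.22) and ASGR2 (-0.90 ± 0.20), chosen after their values were seen. Since the list was written after some of these values were known, it was also tested on the members not seen before. Of these 27, 2 fell (5 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 3.24e-04, adjusted p = 0.396 with an estimated correlation, fry adjusted p = 0.108). Among these the groups overlapped, with control replicate 3 at -0.37, below knockdown replicate 3 at -0.31. The 3 control libraries also differed among themselves, with medians of the whole list of 0.24, 0.10 and -0.37 relative to the control mean. The hepatocyte genes AFP and HNF4A were at 5352 and 275 CPM or more in every library (without TMM scaling). The median level was 86.4 CPM for the liver list, 0.648 for the prostate list and 0.0896 for the lung list. These levels argue against the lung or prostate origin that the labels and the line's name give. Which line was sequenced was not tested.

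Knockdown replicate 1 differed from the other knockdown libraries, with the ATF4 list at a median excess of 1.21 (27 of 32 genes higher). Other lists also lay beyond nearly all of 10000 random lists in this library: Notch (0.72), microRNA machinery (0.58), immediate early genes (0.52), histones (-1.37), cholesterol synthesis (-1.06), heat shock (-0.74), ribosomal proteins (-0.57), the respiratory chain (-0.44) and mitosis (-0.41). These values are relative to knockdown replicates 2 and 3, which carried a trend with transcript length. MicroRNA machinery and ribosomal proteins lay nearer the controls in replicate 1 (-0.06 and -0.11) than in replicates 2 (-0.32 and 0.32) and 3 (-0.43 and 0.52). Random lists hold unrelated genes, so lists whose genes move together lie beyond them more readily. The length trend was removed for the ATF4 list only. A weaker knockdown in replicate 1 is argued against by its IGF2BP3 level of 19.3 CPM, the lowest of the 3. A trend with transcript length is argued against for the ATF4 list by an excess of 1.07 with the trend removed. What set this library apart stays open, with an amino acid response in that culture not tested separately and no batch in the labels, and it also held 27139 genes with at least 1 count (24119 to 25159 in the other 5), a share of 4.27% in its 10 most abundant genes (5.81% or more elsewhere) and 0.215% in mitochondrial pseudogenes (0.393% to 0.475% elsewhere).

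Fold changes fell with transcript length across genes (Spearman rho -0.234, genes not being independent replicates), with a median of 0.18 in the shortest 20% of genes and -0.17 in the longest 20%; without knockdown replicate 1 these were -0.339, 0.25 and -0.29. The trend alone is argued against as the source of the calls, since 67.84% of the called genes stayed called with it removed. Recovery of long transcripts that differed between libraries independently of the siRNA stays open. The lowest control slope minus the highest knockdown slope was -0.0247 per doubling of length, so the groups overlapped, with knockdown replicate 1 at 0.055 above the controls at 0.030 to 0.050 and knockdown replicates 2 and 3 at -0.061 and -0.119. An effect of the siRNA on long transcripts also stays open, untested.

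The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split with as many results: 625 genes against 0 at most in the others, 333 genes at 2-fold or more against 0, and 17 lists against 14. Every other split mixes control and knockdown libraries, so a difference between the real groups widens its spread and lowers its count. The 0 therefore does not measure what chance gives.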
